A study of Homo sapiens with 6 samples.

How the data were processed

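DMS114 cells, an established small cell lung cancer line, were exposed to 2.5 mM β-alanine or vehicle for 48 h, with 3 libraries per group, per the labels. Per the labels' protocols, RNA was extracted with Trizol and column purification, samples with an RNA integrity number above 7.0 were kept, and libraries were made with the TruSeq RNA Sample Preparation Kit and read on a NovaSeq X Plus. Groups and replicate numbers were taken from the sample titles.

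The authors deposited raw counts per gene symbol in a single table of 36458 symbols. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic 0.39, STAR 2.7.3a, featureCounts 2.0.1 and DESeq2, with genome build GRCh38. Their settings, the annotation and the use of strand are not given in the sources used here. All values were whole numbers of at least 0, no row lacked a gene name, and 3198 symbols had no count in any library. Since strand was not stated, genes that overlap on opposite strands cannot be told apart, and near-identical copies can share or lose reads.

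Genes were filtered with filterByExpr, leaving 17331, and library sizes were scaled by TMM. The main test was edgeR 4.0.16's quasi-likelihood test with robust shrinkage in R 4.3.3, on all 6 libraries with no covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 of β-alanine over control with their standard errors, and CPM uses the TMM-scaled totals. The common dispersion was 0.00189, a biological coefficient of variation of 4.35%. Gene positions came from RefSeq on GRCh38.p14, and strand, GC content and length from GENCODE release 29, which gave a GC value for 97.82% of tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

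Gene lists were fixed before the data were examined: 55 lists on β-alanine handling, metabolism, stress, proliferation, signalling, immune, neural and adhesion functions, markers of other cell types and RNA quality. The 50 with at least 5 measured members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 50. Member counts are given over all genes tested and adjusted over the list alone. The rule for named genes was fixed at the same time. It took STMN2 and the called genes of the β-alanine list, the 10 largest rises and falls, and the 5 smallest p-values in each direction. Parts of the rule on size and p required an average log2 CPM of at least 1, a regular symbol and full separation of the 2 groups. For each list described, up to 4 members with the smallest p were named. PHGDH and NCAM1, which fell within their lists, and the subtype factors YAP1, NEUROD1 and POU2F3 were named after their values were seen.

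Depth ran from 14433801 to 32909568 counts per library. On simulated counts with the same means and library sizes (17119 genes), the test recovered 58% of 50 genes changed 1.25-fold, 72.9% of 48 changed 1.5-fold, 90% of 50 changed 2-fold and 97.9% of 48 changed 3-fold. Of 168 simulated calls, 12 were false. The camera step with the preset correlation called the list that had been shifted and 1 other. Camera with an estimated correlation called the shifted list (adjusted p = 0.0144) and 0 others. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called falsely.

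Alternatives were other scaling factors, library totals, other low-count filters, DESeq2 1.42.0, limma-voom, no robust shrinkage, a replicate block, stricter thresholds, protein-coding genes, camera with an estimated correlation, fry and leaving out each library. A GC correction, thinning to the smallest library, and list counts without each library were added after seeing the data. No library was left out of the main test.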

Results

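The series measured polyadenylated RNA in DMS114, an established human small cell lung cancer line, after exposure to 2.5 mM β-alanine for 48 h or to an equal volume of vehicle. β-alanine is an amino acid that is not built into proteins and enters cells through the taurine transporter. Each condition had 3 libraries. Total counts over 36458 gene symbols were 14433801, 27324339 and 32909568 in β-alanine libraries 1, 2 and 3, and 18814876, 22072654 and 19613283 in control libraries 1, 2 and 3. Libraries of one group differed by more than sampling noise, with a chi-square per gene of 1.97 to 4.86, against 4.69 to 15.9 between groups. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

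The comparison of β-alanine with vehicle asked which transcripts the compound alters in a line from a study on stathmin 2, β-alanine metabolism and neuronal invasion. Among well-measured genes with full separation of the groups, the largest rises included the protease gene PLAT and immediate-early transcription factors. These factors were the NR4A nuclear receptors, EGR1 and FOS. Genes of NF-kB signalling, antigen presentation, interferon response, histones, lysosomes, the amino acid response, heat shock and p53 were also higher as groups in limma's camera with a preset correlation, but not with an estimated one (adjusted p between 0.37 and 0.444). DNA replication and mitosis genes, ribosomal protein genes, extracellular matrix genes and axon guidance genes were lower as groups in the same test, and these calls were also lost (adjusted p between 0.37 and 0.605 with an estimated correlation in limma's camera). In β-alanine library 1 the replication and mitosis lists lay at -0.02 and -0.01 relative to controls on the log2 scale. NR4A1, an orphan nuclear receptor induced by many stimuli, rose from 8.58 ± 1.06 to 50.7 ± 6.83 CPM (SD, n = 3 per group).

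Of 17331 genes tested, 2441 rose and 2389 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This was 27.87% of tested genes, the share against which the member counts of gene lists are to be read. Most changes were small, with a median absolute log2 fold change of 0.28 among the genes called. A log2 change of at least 1 was reached by 115 genes that rose and 66 that fell. All 3 treated libraries lay on one side of all 3 controls for 39.1% of tested genes, against the 10% that chance gives. The counts fell to 1501 and 1473 without β-alanine library 2, and to 1570 and 1488 without control library 2.

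**Figure D1:**
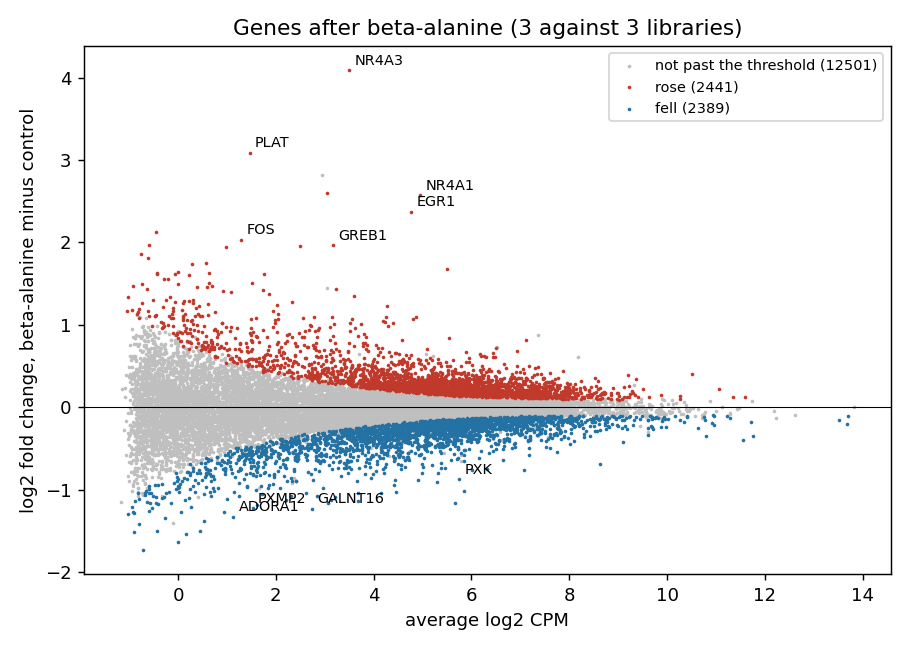
Log2 fold change of β-alanine over control against average log2 CPM for each of 17331 tested genes, with 3 libraries per group. Red points are the 2441 genes that rose, blue points the 2389 that fell and grey points those that did not pass; NR4A3 has the highest labelled point, at 4.09.

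The 10 largest rises among well-measured genes included 3 members of the NR4A family. NR4A3 rose by a log2 of 4.09 ± 0.60 (SE), NR4A2 by 2.60 ± 0.26 and NR4A1 by 2.57 ± 0.11, the last with an adjusted p of 7.94e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a rise in 3 of 3 libraries. EGR1, a zinc finger factor, rose by 2.37 ± 0.38 and FOS, a subunit of the AP-1 factor, by 2.03 ± 0.23. PLAT, which encodes tissue plasminogen activator, rose by 3.09 ± 0.67. GREB1 rose by 1.97 ± 0.34, MAP3K14, the NF-kB-inducing kinase, by 1.68 ± 0.29, PRRG2 by 1.62 ± 0.20 and ARHGAP31 by 1.51 ± 0.31. NR4A1, MAP3K14 and ARHGAP31 overlap genes annotated as antisense (NR4A1AS, MAP3K14-AS1 and ARHGAP31-AS1), and NR4A1, GREB1 and ARHGAP31 overlap other annotated genes, so their counts are uncertain, since the counting was not stated to use strand. NR4A1 lies on chromosome 12 from 52022832 to 52059503, NR4A3 on chromosome 9 from 99821885 to 99866891, EGR1 on chromosome 5 from 138465479 to 138469303 and FOS on chromosome 14 from 75278828 to 75282230 (GRCh38, RefSeq). The calls for NR4A3, EGR1, PLAT and MAP3K14 were lost in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment when any one of the 3 controls was left out. Those of EGR1, PLAT and MAP3K14 were also lost without β-alanine library 3, and that of MAP3K14 without β-alanine library 2. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p-values of these 4 genes then lay between 0.0531 and 0.094, and that of GREB1 was 0.0522 without control library 1. The calls for NR4A3 (adjusted p = 0.0501) and PLAT (0.0942) were also lost with limma-voom on all 6 libraries.

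The 10 largest falls were smaller. ADORA1, the adenosine A1 receptor, fell from 3.11 ± 0.45 to 1.24 ± 0.04 CPM (SD, n = 3 per group), a log2 change of -1.33 ± 0.20 (SE). GALNT16, a glycosyltransferase, changed by -1.23 ± 0.15, PXMP2, a peroxisomal membrane protein, by -1.22 ± 0.25, and SFRP5, a secreted Wnt antagonist, by -1.19 ± 0.22. TMEM132A changed by -1.17, EEF1AKMT2 by -1.16, RASL10B by -1.13, FXYD6 by -1.13, ITGA9-AS1 by -1.12 and TTC26 by -1.09. ITGA9-AS1 lies antisense to ITGA9, so its reads cannot be told from those of ITGA9 without strand. GALNT16 overlaps GALNT16-AS1 and ERH, FXYD6 overlaps FXYD6-AS1, and PXMP2, TMEM132A and TTC26 also overlap other annotated genes, so their counts are uncertain as well. The call for TMEM132A was lost without β-alanine library 2 (adjusted p = 0.0791 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), control library 1 (0.0521) or control library 3 (0.0516).

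The smallest p-values for rises belonged to NR4A1, IER2, STX10, C2CD2L and UPF3B. IER2, an immediate-early gene, rose from 61.9 ± 1.55 to 94.2 ± 2.81 CPM, and STX10, a syntaxin of the Golgi, from 70.7 ± 2.37 to 107 ± 5.84 CPM (SD, n = 3 per group). C2CD2L rose by a log2 of 0.99 ± 0.08 (SE) and UPF3B, a factor in nonsense-mediated decay, by 0.65 ± 0.06. For falls they belonged to PXK, POFUT1, WDR11, PLAGL2 and EFNB3, each with an adjusted p of 1.33e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and lower values in 3 of 3 libraries. Of these 10, UPF3B, PXK, POFUT1 and WDR11 overlap other annotated genes, as does NR4A1. PXK fell from 69.5 ± 4.52 to 38.4 ± 3.38 CPM, and POFUT1, which adds O-fucose to Notch receptors, from 122 ± 4.27 to 79.0 ± 4.03 CPM.

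**Figure D2:**
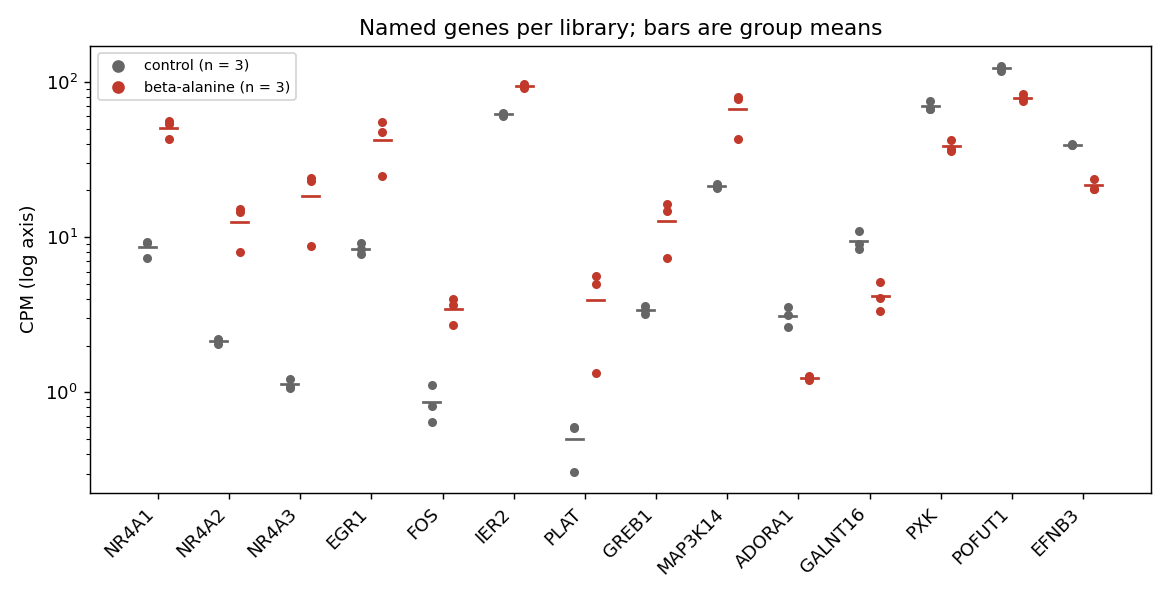
CPM per library on a log axis for 14 named genes, with grey points for the 3 control libraries, red points for the 3 β-alanine libraries and bars at group means. NR4A1 averages 50.7 CPM after β-alanine and 8.58 in controls, and PXK 38.4 and 69.5.

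STMN2, the stathmin named in the study title, was near the detection floor in both groups. It had 1, 2 and 4 counts in the β-alanine libraries and 3, 1 and 4 in the controls, and was not tested. The pooled levels were 0.0937 CPM (95% Poisson interval 0.0377 to 0.193) and 0.132 CPM (0.0571 to 0.261), so no difference was detectable at this depth. These intervals cover counting error only.

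Of 21 measured genes for β-alanine transport and metabolism, 5 rose and 1 fell, and the same counts held adjusted over the list alone. This is near the 27.87% called over all tested genes, so the count does not set the list apart. The taurine and β-alanine transporter SLC6A6 rose by a log2 of 0.24 ± 0.06 (SE) and the proton-coupled amino acid transporter SLC36A1 by 0.23 ± 0.06. SLC36A4 rose by 0.22 ± 0.07. SLC6A6, SLC36A1 and PANK3 overlap other annotated genes, among them GRIP2 for SLC6A6. PANK3 and COASY, enzymes of coenzyme A synthesis, rose by 0.17 ± 0.04 and 0.24 ± 0.05. CARNS1, which joins β-alanine to histidine to form carnosine, changed by -0.61 ± 0.18, from 3.79 to 2.45 CPM. As a group the list did not pass limma's camera test with Benjamini-Hochberg adjustment (adjusted p = 0.341). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the calls for SLC6A6 (adjusted p = 0.0651), SLC36A1 (0.0618) and SLC36A4 (0.187) were lost without control library 2, and that for CARNS1 without β-alanine library 2 (0.111) or control library 1 (0.0895). SLC36A4 also lost its call without β-alanine library 2 (0.0579), β-alanine library 3 (0.233) or control library 1 (0.0773), and with the DESeq2 Wald test (0.0797), a GC correction (0.0807) or thinning to the smallest library (0.393). Thinning also ended the call of CARNS1 (adjusted p = 0.0533 in edgeR's quasi-likelihood test).

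Of 55 gene lists, 50 had at least 5 measured members, and 19 of these passed limma's camera test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment. None of the 19 held when camera estimated the correlation within each list, where the smallest adjusted p was 0.37, 6 lists had an unadjusted p under 0.05, and limma's fry called 19. The estimated correlation lay below the preset 0.01 for p53 targets (-0.0373), the amino acid response (-0.0224) and neural cell adhesion (0.00578). A higher correlation therefore cannot account for the loss of these calls. In the other lists called it ran from 0.0102 to 0.768. By fry, which tests whether a list moves on balance and does not compare it with other genes, 6 of the 19 camera lists did not pass with Benjamini-Hochberg adjustment: S phase (adjusted p = 0.109), mitosis (0.144), ribosomal proteins (0.122), mitochondrially encoded genes (0.223), interferon (0.0574) and antigen presentation (0.0576). β-alanine library 1 stood apart from libraries 2 and 3, at -9.14 on the first principal component against -23.5 and -23.6, with control libraries 1, 2 and 3 at 20.02, 19.54 and 16.71. The count of members that rose or fell moved by over 1.5 times in 8 of the 19 lists without β-alanine library 1, in 11 and 13 without β-alanine libraries 2 and 3, and in 8, 9 and 4 without control libraries 1, 2 and 3.

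All 22 immediate-early and AP-1 genes were measured, of which 16 rose and none fell, with the same 16 adjusted over the list alone. Besides NR4A1, IER2 and FOS, the bZIP factor MAFF rose by a log2 of 1.35 ± 0.13 (SE). The median log2 change was 1.04 (camera adjusted p = 1.58e-10 with Benjamini-Hochberg adjustment, and adjusted p = 0.371 with an estimated correlation). The list mean was 0.82, 1.29 and 1.22 above the control mean on the log2 scale in β-alanine libraries 1, 2 and 3. Among 14 feedback targets of MAPK signalling, 6 rose and 1 fell, against 8 and 1 adjusted over the list alone. ETV4 rose by 0.76 ± 0.08, SPRY4 by 0.43 ± 0.07 and SPRY2 by 1.28 ± 0.29, while CCND1, which encodes cyclin D1, changed by -0.16 ± 0.03. In camera the group passed (adjusted p = 0.00281, Benjamini-Hochberg), with adjusted p = 0.37 with an estimated correlation. Its mean was 0.24, 0.42 and 0.45 above controls in β-alanine libraries 1, 2 and 3.

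NF-kB, antigen presentation and interferon genes were higher in β-alanine libraries 2 and 3, with a smaller shift in library 1. Of 8 NF-kB targets measured, 5 rose, and 8 adjusted over the list alone. RELB and NFKB1, subunits of the factor, rose by log2 values of 0.75 ± 0.11 and 0.45 ± 0.07 (SE). By camera the list was called (adjusted p = 1.14e-05, Benjamini-Hochberg), with adjusted p = 0.421 with an estimated correlation. Of 14 antigen presentation genes, 9 rose, and 11 adjusted over the list alone, among them the peptide transporters TAP1 (0.39 ± 0.06) and TAP2 (0.33 ± 0.06), HLA-E (0.22 ± 0.04) and HLA-C (0.41 ± 0.07). HLA genes are similar in sequence, so their counts are uncertain. The camera test called the list (adjusted p = 1.78e-06, Benjamini-Hochberg), with adjusted p = 0.44 with an estimated correlation. Of 25 interferon response genes, 11 rose both over all genes and adjusted over the list alone, including ISG15 (0.27 ± 0.05), IRF7 (0.81 ± 0.16) and PARP9 (0.62 ± 0.14). This list passed camera (adjusted p = 0.000117, Benjamini-Hochberg), with adjusted p = 0.444 with an estimated correlation. In β-alanine libraries 1, 2 and 3, list means relative to controls were 0.25, 0.74 and 0.75 for NF-kB, 0.10, 0.42 and 0.46 for antigen presentation, and 0.06, 0.36 and 0.33 for interferon. The interferon list stood at 0.05, 0.05 and -0.10 in control libraries 1, 2 and 3, so β-alanine library 1 lay at the level of controls 1 and 2. Without β-alanine library 1, all 8 of these NF-kB genes and 13 of the 14 antigen presentation genes rose. Without β-alanine library 2 or 3, 2 NF-kB and 5 antigen presentation genes rose, and without control libraries 1, 2 and 3, 3, 3 and 2 of the 8 NF-kB genes rose.

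Replication genes were lower in β-alanine libraries 2 and 3. Of 30 S-phase genes, 16 fell and none rose, and 18 fell adjusted over the list alone. The helicase subunits MCM5 and MCM2 changed by log2 values of -0.44 ± 0.06 and -0.38 ± 0.07 (SE), UHRF1 by -0.44 ± 0.07 and CDC6, which loads the helicase, by -0.38 ± 0.08. Camera gave a call for the set (adjusted p = 1.54e-07, Benjamini-Hochberg), with adjusted p = 0.558 with an estimated correlation. Of 30 genes of G2 and mitosis, 10 fell and 3 rose, against 14 and 3 adjusted over the list alone. PLK1, a mitotic kinase, changed by -0.32 ± 0.06 and MKI67 by -0.22 ± 0.04, while the kinesin KIF20A rose by 0.20 ± 0.04. This list passed camera (adjusted p = 0.000978, Benjamini-Hochberg), with adjusted p = 0.605 with an estimated correlation. The S-phase mean relative to controls was -0.02 in β-alanine library 1 against -0.29 and -0.28 in libraries 2 and 3, and that of the mitotic list was -0.01 against -0.16 and -0.16. Without β-alanine library 1, 26 S-phase and 20 mitotic genes fell. Without β-alanine library 2 or 3 or control library 1 or 2, 7 to 9 S-phase genes fell, and 6 mitotic genes fell without β-alanine library 2 or 3 or control library 2.

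Replication-dependent histone transcripts, which mostly lack a poly(A) tail, were higher. Of 14 measured, 11 rose, and 11 adjusted over the list alone, with a median log2 change of 0.69. H2AC11 rose by 0.71 ± 0.10 (SE), H2BC11 by 1.07 ± 0.17, H3C10 by 1.09 ± 0.16 and H2AC6 by 0.49 ± 0.09. Histone copies are near-identical, so counts for single members are uncertain. As a set these genes passed camera (adjusted p = 1.22e-06, Benjamini-Hochberg), with adjusted p = 0.371 with an estimated correlation. The list mean was 0.40, 0.67 and 0.69 above controls in β-alanine libraries 1, 2 and 3. Summed CPM of 17 small structural RNAs without a poly(A) tail was 17.1 ± 2.48 after β-alanine and 10.1 ± 0.183 in controls (SD, n = 3 per group).

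Lysosome and autophagy genes were higher, with 14 of 24 rising and none falling, and 15 rising adjusted over the list alone. GABARAPL1 and MAP1LC3B, components of the autophagosome, rose by log2 values of 0.54 ± 0.05 and 0.41 ± 0.05 (SE). TFE3, a transcription factor of lysosomal genes, rose by 0.44 ± 0.05 and the cholesterol exporter NPC1 by 0.39 ± 0.06. In the camera test the list passed (adjusted p = 6.17e-06, Benjamini-Hochberg), with adjusted p = 0.371 with an estimated correlation. Its mean was 0.11, 0.21 and 0.21 above controls in β-alanine libraries 1, 2 and 3, and 9 genes rose without β-alanine library 3.

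Amino acid response, heat shock and p53 target genes shifted by similar amounts in all 3 β-alanine libraries. Of 32 amino acid response genes driven by ATF4, 16 rose and 5 fell, against 16 and 6 adjusted over the list alone. CHAC1, a glutathione-degrading enzyme, rose from 4.77 ± 0.38 to 9.15 ± 0.09 CPM (SD, n = 3 per group). SHMT2 and GARS1 rose by log2 values of 0.31 ± 0.04 and 0.27 ± 0.04 (SE), and ATF3, which is also on the immediate-early list, by 1.94 ± 0.28. The serine synthesis enzymes PSAT1 and PHGDH fell, the latter by 0.25 ± 0.06. Camera called this set (adjusted p = 0.00472, Benjamini-Hochberg), with adjusted p = 0.37 with an estimated correlation. Of 13 heat shock genes, 9 rose and 1 fell, with the same counts adjusted over the list alone, including HSP90AA1 (0.22 ± 0.04), BAG3 (0.30 ± 0.05) and HSPB1 (0.26 ± 0.05). HSPA1A rose by 0.57 ± 0.11, but shares reads with its copy HSPA1B. This list passed camera (adjusted p = 0.000888, Benjamini-Hochberg), with adjusted p = 0.37 with an estimated correlation. Of 21 p53 targets, 10 rose and 1 fell, against 11 and 2 adjusted over the list alone, among them ZMAT3 (0.50 ± 0.06), TNFRSF10B (0.27 ± 0.05) and BTG2 (0.41 ± 0.08). The p53 list passed camera (adjusted p = 0.0116, Benjamini-Hochberg), with adjusted p = 0.37 with an estimated correlation. List means relative to controls in β-alanine libraries 1, 2 and 3 were 0.17, 0.19 and 0.18 for ATF4, 0.16, 0.17 and 0.14 for heat shock, and 0.14, 0.16 and 0.14 for p53. Without control library 2, 5 of the p53 targets rose, and 3 amino acid response genes fell without β-alanine library 2 or 3 or control library 1 or 2.

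**Figure D3:**
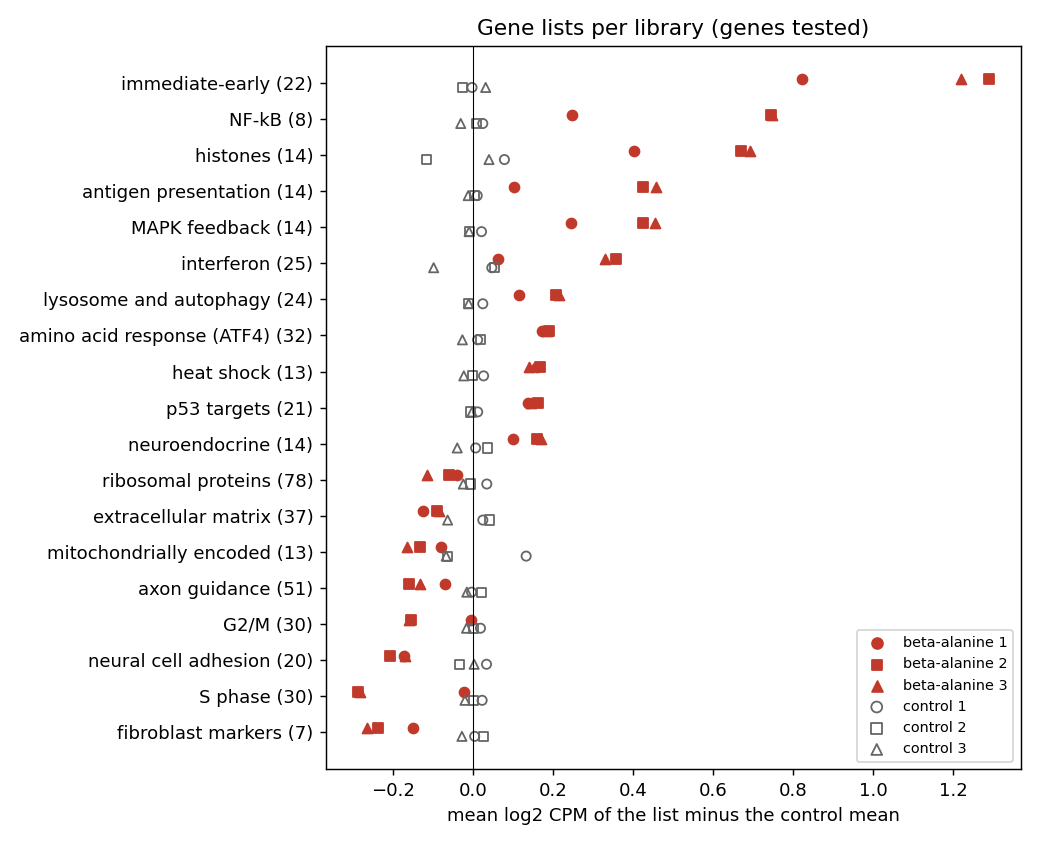
Mean log2 CPM of each of the 19 lists that passed camera with the preset correlation, minus the mean of the 3 controls, for each library (filled symbols, β-alanine; open symbols, control; number of genes in parentheses). The S-phase list lies at -0.02 in β-alanine library 1 and at -0.29 and -0.28 in libraries 2 and 3, while the ATF4 list lies at 0.17, 0.19 and 0.18.

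Matrix, axon guidance and cell adhesion genes were lower. Of 37 extracellular matrix genes, 18 fell and 6 rose, against 21 and 7 adjusted over the list alone. With the DESeq2 Wald test, 15 fell and 2 rose. The collagens COL3A1 and COL5A2 changed by log2 values of -0.34 ± 0.04 and -0.24 ± 0.04 (SE) and the membrane protease MMP15 by -0.54 ± 0.08, while THBS1 rose by 0.73 ± 0.13. The set as a whole passed camera (adjusted p = 0.00281, Benjamini-Hochberg), with adjusted p = 0.37 with an estimated correlation. Of 51 axon guidance genes, 17 fell and 2 rose, against 19 and 2 adjusted over the list alone. EFNB3, an ephrin ligand, changed by -0.89 ± 0.07, SEMA5A by -0.35 ± 0.05, SEMA3C by -0.32 ± 0.05 and EFNA1 by -0.43 ± 0.08. The guidance list passed camera (adjusted p = 0.000449, Benjamini-Hochberg), with adjusted p = 0.37 with an estimated correlation. Of 20 neural cell adhesion genes, 6 fell and 1 rose, against 7 and 1 adjusted over the list alone. CDH4 changed by -0.94 ± 0.15 and CADM1 by -0.38 ± 0.07, and PCDH7 rose by 0.41 ± 0.08. This list passed camera narrowly (adjusted p = 0.049, Benjamini-Hochberg), with adjusted p = 0.371 with an estimated correlation. Its call was lost in limma's camera with Benjamini-Hochberg adjustment without β-alanine library 1 (adjusted p = 0.0908), β-alanine library 2 (0.0689), control library 1 (0.0946) or control library 3 (0.0641), and with a filter of at least 1 CPM in 3 libraries (0.0613). Of 7 fibroblast markers, which this line itself expressed (COL3A1 at 876 ± 23.5 CPM in controls), 4 fell and 1 rose, both over all genes and adjusted over the list alone. The markers passed camera (adjusted p = 0.0063, Benjamini-Hochberg), with adjusted p = 0.421 with an estimated correlation. In β-alanine libraries 1, 2 and 3, list means relative to controls were -0.13, -0.09 and -0.09 for matrix, -0.07, -0.16 and -0.13 for axon guidance, -0.17, -0.21 and -0.17 for neural adhesion, and -0.15, -0.24 and -0.27 for the fibroblast markers. The matrix list stood at 0.02, 0.04 and -0.06 in control libraries 1, 2 and 3, so β-alanine libraries 2 and 3 lay close to control library 3. Without β-alanine library 2 or 3 or control library 3, 3 matrix genes rose, without control library 2, 10 matrix genes fell, without β-alanine library 3, 11 guidance genes fell, and without control library 1, 3 neural adhesion genes fell.

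Neuroendocrine markers were higher, with 6 of 14 rising and 1 falling, the same adjusted over the list alone. SYP, the vesicle protein synaptophysin, rose from 61.0 ± 4.23 to 86.3 ± 4.26 CPM (SD, n = 3 per group). The granins CHGA and CHGB rose by log2 values of 0.56 ± 0.08 and 0.32 ± 0.06 (SE) and SCG3 by 0.61 ± 0.09, while NCAM1 fell. The group test, camera, called the list (adjusted p = 0.0147, Benjamini-Hochberg), with adjusted p = 0.371 with an estimated correlation. Its mean was 0.10, 0.16 and 0.17 above controls in β-alanine libraries 1, 2 and 3. Among transcription factors used to describe small cell lung cancer subtypes, YAP1 stood at 124 ± 4.91 CPM in controls and NEUROD1 at 2.28 ± 0.478 (SD, n = 3), while POU2F3 was below the expression filter.

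Ribosomal protein genes and mitochondrially encoded genes were slightly lower. Of 78 ribosomal protein genes, 22 fell and none rose, the same adjusted over the list alone, with a median log2 change of -0.07. RPL10A changed by -0.27 ± 0.04 (SE) and RPL10 by -0.24 ± 0.04. Pseudogene copies make single counts uncertain. By camera these genes were called (adjusted p = 5.9e-06, Benjamini-Hochberg), with adjusted p = 0.605 with an estimated correlation, and 39 fell without β-alanine library 1, against 8 to 12 without β-alanine library 2 or 3 or control library 1 or 2. Its mean relative to controls was -0.04, -0.06 and -0.12 in β-alanine libraries 1, 2 and 3. Of 13 mitochondrially encoded genes, 5 fell and none rose, the same adjusted over the list alone, including MT-ND5 (-0.40 ± 0.09) and MT-ATP8 (-0.18 ± 0.04). Mitochondrial genes took 5.38% to 5.60% of counts after β-alanine, 5.62% in control libraries 2 and 3 and 6.32% in control library 1. The list mean relative to the control mean was -0.08, -0.13 and -0.17 in β-alanine libraries 1, 2 and 3, and 0.13, -0.06 and -0.07 in control libraries 1, 2 and 3. This list passed camera (adjusted p = 0.00164, Benjamini-Hochberg), with adjusted p = 0.605 with an estimated correlation, and lost its call in limma's camera without control library 1 (adjusted p = 0.0946). Then 2 of its genes fell, as without β-alanine library 3, against 1 without β-alanine library 2.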

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

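The GC correction, the thinning and the list member counts without each library were chosen after seeing the data. The counts of 2441 genes that rose and 2389 that fell in edgeR stayed within 1.5 times under every other scaling, filter and tool tried, down to 1763 and 1798 with the DESeq2 Wald test and up to 2745 that rose with library totals. An adjusted p of 0.01 gave 1454 and 1391, and an absolute log2 change of at least 1 gave 115 and 66, both stricter by construction. Leaving out 1 library gave 1501 to 3204 that rose and 1473 to 3294 that fell, lowest without β-alanine library 2 and highest without β-alanine library 1, and 17 to 19 lists; the cause was not tested. Thinning all libraries to the smallest gave 1785 and 1719, so depth limits the count. Whether the replicate numbers pair the samples could not be decided from 3 libraries per group. Correlations between libraries of one number were 0.0496, 0.00365 and 0.0716, with libraries 1 and 3 matching their own number best. A replicate block gave 2564 that rose, 2608 that fell and 18 lists, neural cell adhesion being the list not called (adjusted p = 0.0682 in limma's camera). Camera with an estimated correlation called 0 of 50 lists, with 6 at an unadjusted p under 0.05, and fry called 19. Of these 19, 13 were shared with the 19 of the preset correlation. A correlation above the preset cannot account for the lost calls of p53 targets, amino acid response and neural cell adhesion, whose estimates lay below 0.01. The cause was otherwise not tested, so a lost call is not by itself evidence of correlation among the genes of a list. Of 206 named genes called, 162 were called under all 17 alternatives and SPRY2 under the 16 that gave it an adjusted p, and no called gene reversed in any of them.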

Other observations

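The tests of RNA mixing and of the immune lists in β-alanine library 1, of S phase, of gene families and of neighbouring genes in general were chosen after the result was seen. The CREB and head-to-head tests followed from results already seen, but were set before their own values were.

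Synaptic vesicle genes, not described above, held large single changes without a group call by camera. Of 37 measured, 10 rose and 3 fell, the same adjusted over the list alone and 11 and 6, 6 and 2, and 6 and 1 without β-alanine library 1, β-alanine library 2 and control library 2, with camera giving an adjusted p of 0.31 after Benjamini-Hochberg adjustment and limma's fry 0.027. SYN1, a vesicle phosphoprotein, rose from 9.61 ± 0.91 to 17.6 ± 1.38 CPM (SD, n = 3 per group), CPLX2, a regulator of vesicle fusion, by a log2 of 1.09 ± 0.15 (SE), and NLGN3, a synaptic adhesion protein, changed by -0.57 ± 0.07. VGF, a secreted neuropeptide precursor, rose by 1.02 ± 0.15, SNAP25 by 1.17 ± 0.18, and RET, a receptor of glial-derived factors, changed by -0.43 ± 0.09. Of 29 stathmin, tubulin and neurite cytoskeleton genes, 5 rose and 4 fell, the same adjusted over the list alone and 5 and 9, and 4 and 2, without β-alanine libraries 1 and 3, including the neurofilament gene INA (0.35 ± 0.05).

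Central metabolism genes were called in both directions, and none of these lists passed camera on all 6 libraries. Over all tested genes 27.87% were called, in both directions, so such calls are not particular to metabolism. Of 33 genes of the tricarboxylic acid cycle and pyruvate use, 9 rose and 8 fell, against 9 and 9 adjusted over the list alone. The cytosolic aspartate aminotransferase GOT1 rose by a log2 of 0.40 ± 0.06 (SE), while its mitochondrial counterpart GOT2 changed by -0.38 ± 0.05 and DLAT, a pyruvate dehydrogenase subunit, by -0.43 ± 0.06. Of 72 nuclear oxidative phosphorylation genes, 8 rose and 13 fell, and of 23 glycolysis genes, 6 rose and 3 fell, against 8 and 13, and 7 and 3, adjusted over the list alone. Without β-alanine library 1, 7 glycolysis genes rose and 6 fell, against 3 and 1 without β-alanine library 2 or control library 2. Without β-alanine library 2, 3 oxidative phosphorylation genes rose, and without control library 2, 5 of the tricarboxylic acid cycle genes rose. PKM changed by -0.23 ± 0.04 and HK1 rose by 0.28 ± 0.05. Of 17 fatty acid synthesis genes, 2 rose and 6 fell, the same adjusted over the list alone. SCD, the stearoyl-CoA desaturase, rose by 0.41 ± 0.05 and ELOVL6, a fatty acid elongase, changed by -0.98 ± 0.18. The camera adjusted p-values after Benjamini-Hochberg adjustment were 0.601, 0.534 and 0.494 for the first 3 lists and 0.0655 for fatty acid synthesis. Without β-alanine library 1 the last list was called (adjusted p = 0.0171 in limma's camera), with 2 that rose and 9 that fell.

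The other 24 lists that limma's camera did not call had adjusted p-values between 0.117 and 0.984 with Benjamini-Hochberg adjustment. Of these, limma's fry called integrins and focal adhesion (adjusted p = 0.0109), ion channels (0.0157), and Wnt targets, osmotic response and mesenchymal genes (0.0322 each). Members that rose and fell, over all genes tested, numbered 1 and 7 of 30 for ion channels, 1 and 4 of 12 for Wnt targets, 3 and 1 of 12 for osmotic response, 3 and 0 of 6 for metallothioneins and zinc, and 4 and 0 of 19 for hypoxia. They were 6 and 2 of 20 for oxidative stress, 2 and 3 of 14 for Notch, 7 and 10 of 26 for integrins and focal adhesion, 2 and 3 of 20 for nucleotide synthesis, and 4 and 4 of 21 for fatty acid oxidation. For mesenchymal genes they were 3 and 5 of 16, for TGF-β targets 5 and 4 of 15, for nuclear-retained RNA 0 and 0 of 6, for cholesterol synthesis 6 and 2 of 24, and for neuron and Schwann cell markers 1 and 0 of 5. For MYC and ribosome biogenesis they were 5 and 3 of 22, for the pentose phosphate pathway 2 and 0 of 7, for neurotransmitter receptors 2 and 3 of 20, for YAP targets 5 and 4 of 21, and for the endoplasmic reticulum stress list 2 and 2 of 20. The last 4 were neurotrophic signalling (4 and 3 of 13), subtype factors (0 and 1 of 6), serine, glycine and one-carbon metabolism (5 and 4 of 19) and mTORC1-related sensing (2 and 1 of 18). Adjusted over the list alone, the counts differed by at most 2 in either direction. Without β-alanine library 1, falls went to 8 for nucleotide synthesis, 6 for Notch, 5 for cholesterol synthesis, 5 for the endoplasmic reticulum list, 5 for MYC, 7 for serine metabolism, 3 for mTORC1, 2 for the pentose phosphate pathway and 1 for neuron and Schwann cell markers. Rises went to 2 for ion channels and 1 for nuclear-retained RNA, and both counts moved for hypoxia (7 and 1) and receptors (4 and 6). Of the 50 lists tested, 24 moved by over 1.5 times in either count without that library, 34 and 31 without β-alanine libraries 2 and 3, and 26, 31 and 20 without control libraries 1, 2 and 3. These small counts therefore depend on single libraries, as in nucleotide synthesis, where 0 rose and 0 fell without β-alanine library 2.

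β-alanine library 1 showed a smaller change than libraries 2 and 3, with, among genes chosen on library 2 or 3 and 1 control and measured on the other controls, 0.481 of the rise and 0.559 of the fall of the remaining treated library. Control RNA mixed into it would give equal shares, and rises lay below falls by a difference of -0.0777 (bootstrap 95% interval -0.125 to -0.0272). Genes chosen on both libraries counted in duplicate and genes are not independent, so this interval is too narrow to decide. Equal shares would also not give S-phase means of -0.02 against -0.29 and -0.28 beside amino acid response means of 0.17 against 0.19 and 0.18. Those lists were picked after their values were seen. For the lower sequencing depth of that library, thinning left the mean change of libraries 2 and 3 at 1.00 of its value. Random loss of reads does this by construction, so the test could not have come out otherwise and decides nothing by itself. Random loss of reads would thus not shrink a mean change, but other effects of a smaller library were not tested. Members of the antigen presentation, interferon and NF-kB lists, which were picked for their low values there, showed a share of 0.211 against 0.605 for other genes that rose (difference -0.394, interval -0.512 to -0.29), which decides nothing, because these other genes were called with that library included. A difference in culture or timing was not tested, because no label records it.

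Of 14 histone genes 11 rose, while 16 of 30 S-phase genes fell, with both list calls lost with an estimated correlation (adjusted p = 0.371 and 0.558 in limma's camera). More cells in S phase would raise both, but the S-phase list was raised in no β-alanine library, while histones were raised in each. S-phase means relative to controls were -0.02, -0.29 and -0.28 in β-alanine libraries 1, 2 and 3, and histone means 0.40, 0.67 and 0.69. The S-phase median was -0.177 (bootstrap 95% interval over genes -0.258 to -0.121). These genes move together (estimated correlation 0.692), so this interval does not measure spread between libraries. For the S-phase list limma's fry gave an adjusted p of 0.109. More non-polyadenylated RNA in the treated libraries is a candidate explanation, since the summed level of 17 small structural RNAs rose by a log2 of 0.748 ± 0.118 (SE), near the histone median of 0.686; without RN7SL1 the change was 0.418 ± 0.128. A change of copy number of the histone region on chromosome 6 (26055740 to 27810536) cannot be told apart, because 19 other genes there had a median log2 change of 0.215 with an interval of 0.0969 to 0.351 that spans the bound set for it. A rise in histone transcription itself was not tested.

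Immediate-early transcripts were higher after 48 h of exposure. The GC trend between the groups did not account for this, since the list median was 1.07 after GC correction against 1.04 before. A general rise of cAMP and CREB target genes was not seen in the 17 tested outside the immediate-early list, whose median of -0.0505 (SD 0.241) lay at percentile 23.8 of 10000 random lists matched on expression (PER1, RGS2 and GEM rose, and NPTX1 and SIK2 fell, these 5 named after their values were seen), while CREB acting on the immediate-early genes alone was not tested. Different handling of treated and control dishes at harvest cannot be told apart from the treatment, as the group means differed by 1.11 against a largest within-group SD of 0.254 and handling by group would look the same. The biological explanation, an effect of β-alanine, remains open for the same reason.

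Neighbouring genes changed together slightly, with a correlation of 0.0641 across 11785 genes in chromosome order, against -0.025 to 0.0321 in 1000 random orders within chromosomes. This used genes with an average log2 CPM above 2 and log2 changes limited to between -1 and 1, and genes are not independent replicates. Log2 changes also followed GC content (Spearman correlation -0.159 over 12198 genes). They were not corrected for it here, and its part in the correlation of neighbours was not tested. The genes with the smallest p-values held 2 head-to-head pairs: STX10 and IER2 on chromosome 19, 32 bp apart, rose by log2 values of 0.604 and 0.608, and PLAGL2 and POFUT1 on chromosome 20, 89 bp apart, changed by -0.646 and -0.635. Over 840 head-to-head pairs at most 1 kb apart the correlation was 0.205, against 0.0523 for 447 tail-to-tail pairs and 0.0523 for 309 pairs on the same strand. The difference of 0.153 from other close pairs (bootstrap 95% interval 0.0528 to 0.25) is consistent with shared promoter regions, although neither transcription starts nor chromatin were measured.

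Families sharing the first letters of their symbol gave 9 camera calls among 238 tested (3.78%). The bound of 5% set for this test decided nothing. Hardly any family would pass an adjusted p by chance if genes were as independent as the preset correlation takes them to be. For the gene lists, the same test called up to 14 of 50 in splits that mixed the groups. Those splits put unequal numbers of treated libraries on their 2 sides, so part of the treatment contrast remained in them. They do not show what the test calls by chance, and the number of family calls to be had by chance is not known. They included collagens (13 of 26 fell, 1 rose, adjusted p = 0.000122 in camera with Benjamini-Hochberg adjustment), tRNA methyltransferases with symbols in TRMT (11 of 16 rose, 1 fell, 0.00403) and proteasome subunits in PSMB (6 of 10 rose, 0.00403). None held in camera with an estimated correlation (adjusted p = 0.902 for each of these 3).

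The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4830 genes and 1 of 10 splits gave as many, with 0 genes in the highest other. It gave 19 lists, again reached by 1 of 10 splits, with 14 in the highest other, which joined β-alanine library 1 with control libraries 1 and 2. That split kept β-alanine libraries 2 and 3 on the same side, so part of the treatment contrast remained in it. The 5 lists with too few measured members for camera were markers of other cell types, in which 1 of 4 simple epithelial, 1 of 3 tuft cell and 0 of 1 erythroid genes rose, none fell, and no leukocyte or squamous marker passed the expression filter. The highest means over all 6 libraries were 0.377 CPM for leukocyte markers (CD14), 0.043 for squamous (S100A2), 0.425 for erythroid (SLC4A1), 13.4 for simple epithelial (MUC1) and 150 for tuft cell markers (SOX9).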
